A study of Homo sapiens with 12 samples.

How the data were processed

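RNA sequencing was done on 12 samples of 2 established human cell lines in 4 groups of 3. H1299 is a non-small-cell lung carcinoma line, and THP-1 is a monocytic leukaemia line that takes on macrophage features after the phorbol ester PMA. The H1299 groups have the genotype labels WT and DCBLD2 overexpression. The WT group is called control here, as the THP-1 labels call it. The genotype labels name no empty construct for it. The THP-1 groups had 24 h of PMA and then 48 h with control or DCBLD2 H1299 cells. The design text speaks of co-culture and the sample labels of supernatant, so whether the cells touched is open. Because DCBLD2 itself went against the H1299 labels, groups are called labelled control and labelled DCBLD2 throughout, and every direction given is labelled DCBLD2 against labelled control.

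Per the labels' protocols, RNA was extracted with Trizol, and enriched mRNA was fragmented and made into libraries with the NEBNext Ultra RNA kit. Per the submitters' processing notes, the tools were fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM, with the hg38 build. Strand handling and the annotation release are not given in the sources used here, so genes that overlap on opposite strands, and near-identical family members, carry uncertain counts. The authors deposited TPM values and estimated counts per gene for each sample, in 1 table of 20307 genes. The estimated counts were not normalized. Over all genes, those at 0 included, between 12.0% and 13.4% of the values per library were not exactly whole, with no tolerance for rounding. No symbol was given for 605 genes. Positions come from GENCODE release 29 on GRCh38, in which 98.9% of the gene identifiers were found.

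The libraries held 14578887 to 23388187 estimated reads in H1299 and 18606739 to 26787853 in THP-1. Estimated counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM scaling and the filterByExpr minimum of 10 counts, in a separate fit of 6 libraries for each cell line. This left 12773 genes in H1299 and 13120 in THP-1. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. TPM means ± SD describe levels, and log2 fold changes ± SE come from the test. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. In THP-1 the replicates lay close to sampling noise, with a chi-square per gene of 1.53 to 2.33 for pairs of one group against 11.4 to 38.8 in H1299. Every pair still differed by more than sampling noise, and all were counted.

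Before the data were examined, 28 gene lists, the tests and the alternatives were fixed. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 and adjustment over the lists of a cell line. Genes named are DCBLD2 and SPP1, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group had at least 5 CPM, and up to 4 called members of each list with the smallest p-values, or 2 members as values where none was called. Genes without a symbol, pseudogenes and read-through models were skipped, and some genes that the rule names are not reported here. The overlap of calls between cell lines was tested per pair of directions with Fisher's exact test, two-sided. RNA carried from H1299 into THP-1 libraries was measured with lists of carcinoma and myeloid genes on log2(CPM + 0.1), with an exact permutation test.

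The steps were tested on simulated counts. In the H1299 simulation of 12731 genes, 50% of genes changed 1.5-fold and 85.9% of those changed 2-fold were recovered, and 7.24% of calls were unchanged genes. In the THP-1 simulation of 13020 genes these values were 86.7%, 92.9% and 4.69%. The seeded interferon list was called higher in both. Of the other lists, 0 were called in the H1299 simulation and 4 in that of THP-1, each of which held a changed gene. Only the interferon list was seeded, so these 4 calls cannot be taken as right. Beside it, 100 and 99 genes changed 1.5-fold and 2-fold in H1299, and 98 and 98 in THP-1, in random directions. These are far fewer than the genes called in the data, and counts were drawn with the trended spread, so the rates may not carry over.

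Alternatives were the replicate number as a block, leaving out each sample, all 12 samples in one fit, DESeq2 1.42.0, its size factors in edgeR, no filter, a mean of at least 10 counts, robust spread, sample weights, a 2-fold threshold, and for lists fry and an estimated correlation. Pseudocount alternatives were planned for a table of normalized values alone and were not run, because counts were given. Transcript structure and read positions were not analysed here.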

Results

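The data are RNA-seq profiles of H1299 lung carcinoma cells and of PMA-treated THP-1 macrophage-like cells, with 12 libraries in 4 groups of 3. The title of the series names SPP1-positive, pro-angiogenic macrophages and the membrane protein DCBLD2 of the tumour cells, and the design sets a control and a DCBLD2 group of H1299 against each other, and THP-1 cells kept for 48 h with either. Libraries held 14578887 to 23388187 estimated reads in H1299 and 18606739 to 26787853 in THP-1.

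DCBLD2, a transmembrane protein with neuropilin-like domains, checks the labels. Its level was lower, not higher, in the H1299 libraries labelled DCBLD2: 98.4 TPM ± 6.03 (SD, n = 3) against 197 TPM ± 49.4 (SD, n = 3) in the libraries labelled control. Single libraries held 105, 98.2 and 92.5 TPM in the labelled DCBLD2 group and 247, 148 and 196 TPM in the labelled control group, so the groups did not overlap. The log2 fold change was -1.27 ± 0.17 (SE), with an adjusted p of 0.00284 by edgeR's quasi-likelihood test. The gene (ENSG00000057019) lies on chromosome 3, 98795941 to 98901689, on the minus strand of GRCh38. In THP-1 libraries DCBLD2 was also lower in the labelled DCBLD2 group, at 6.47 TPM ± 0.175 (SD, n = 3) against 11.9 TPM ± 0.406 (SD, n = 3). The THP-1 cells were not labelled as overexpressing DCBLD2, so their own level does not check the labels. All directions below follow the labels, which this gene contradicts in H1299.

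**Figure D1:**
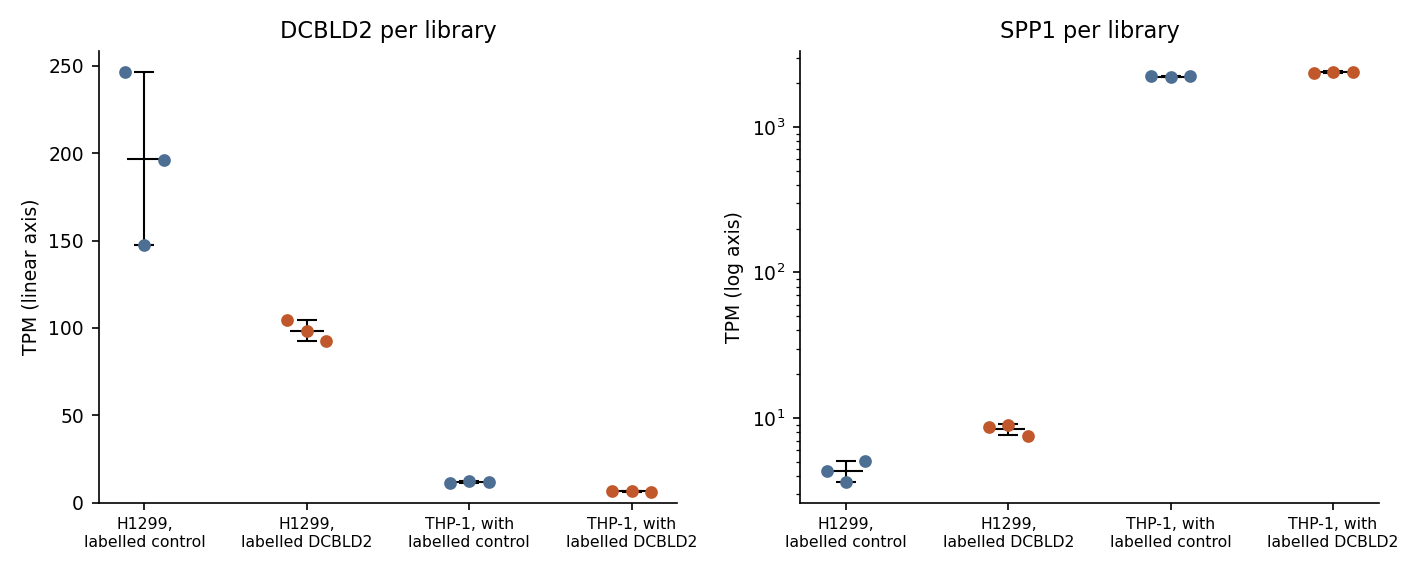
TPM of DCBLD2 (linear axis) and SPP1 (log axis) in each of the 12 libraries by group, with points for libraries and black bars for the mean and SD. DCBLD2 lies between 92.5 and 105 TPM in H1299 labelled DCBLD2, below all 3 libraries labelled control, while SPP1 lies between 2202 and 2399 TPM in the 6 THP-1 libraries.

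In H1299, SYN3 and SNAPC1 were among the largest rises, and NEFH and NRP1 were among the largest falls. SYN3, a synaptic vesicle protein, rose from 3.72 TPM ± 1.24 (SD, n = 3) to 22.9 TPM ± 1.12 (SD, n = 3), a log2 fold change of 2.61 ± 0.21 (SE). The gene (ENSG00000185666) lies on chromosome 22, 32512552 to 33058372, on the minus strand. SNAPC1, a subunit of the small nuclear RNA activating complex, rose by 1.86 ± 0.15 (SE) on the log2 scale to 65.0 TPM. GRIN2B (5.47), TMPRSS15 (2.50), LRRK1 (2.12), RELN (1.99), GFRA1 (1.93), GATM (1.89) and ZNF404 (1.85) made up the other large rises, given as log2 fold changes, and GRIN2B stayed low, at 0.0147 TPM against 1.06 TPM. KRTAP4-7, a hair keratin-associated protein, had 805 reads over the 3 libraries labelled DCBLD2 and 1 read over the 3 labelled control, a ratio of 935 per read sequenced with a 95% counting interval of 167 to 36977 (exact binomial). This interval covers counting error only. In THP-1 the gene had 40 reads in labelled DCBLD2 and 0 in labelled control, at least 12.4-fold higher against a floor of 3 counts over the group. The neurofilament gene NEFH (log2 fold change -3.76), the VEGF co-receptor NRP1 (-3.17), the transcription factor PITX1 (-2.93), the prostaglandin transporter SLCO2A1 (-2.85), PMEPA1 (-2.67), STAT6 (-2.35), IGFBP4 (-2.24), the gelatinase MMP2 (-2.22) and ADGRF1 (-2.19) were among the largest falls. In TPM the falls of NRP1 (4.56 to 0.964) and MMP2 (3.64 ± 2.74 to 1.15 ± 0.118, SD, n = 3) were smaller than in counts. MMP2 lost its call in edgeR without labelled DCBLD2 replicate 1 or 2 (adjusted p of 0.0586 and 0.0996).

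In all, 1313 genes were higher and 1356 lower of 12773 tested in H1299, and 189 and 258 of these changed at least 2-fold. The groups did not overlap for 41.5% of genes, where chance gives 10%. The count rests partly on single libraries: it was 514 without labelled DCBLD2 replicate 2, 1374 without labelled DCBLD2 replicate 1 and 1649 without labelled control replicate 3. Calls of single genes rest on them too. Of 96 H1299 genes chosen by the rule for naming, 45 lost their call without labelled DCBLD2 replicate 2, 22 without replicate 1 and 15 without replicate 3 of that group. The losses were 17 without labelled control replicate 3, 7 without replicate 2 and 4 without replicate 1.

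Of 25 lists tested in H1299, the list of the unfolded protein and integrated stress response was higher, with 7 of 27 members higher, 0 lower and 20 not called, a median log2 fold change of 0.38 and an adjusted p of 0.000226 (camera). The call was lost with an estimated correlation (adjusted p = 0.998) and with fry (adjusted p = 0.105). Adjusted over the list alone, 13 members were higher. ASNS, the asparagine synthetase, rose by 1.23 ± 0.23 (SE) on the log2 scale, and the endoplasmic reticulum chaperones HSPA5 (1.11), HSP90B1 (1.03) and PDIA6 (0.33) rose as well. Each of the 9 other ways to split the 6 libraries into groups of 3 called between 2 and 7 lists with the same test, against 1 list for the labels.

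The remaining H1299 lists that were tested were not called. Of 28 angiogenic factors, 5 were higher and 4 lower (adjusted over the list alone 7 and 6): the matricellular protein CCN1 rose by 1.14 and the chemokine CXCL2 by 0.77 on the log2 scale, while NRP1 fell. SPP1, which encodes the secreted phosphoprotein osteopontin, rose from 4.34 TPM ± 0.713 to 8.37 TPM ± 0.736 (SD, n = 3), a log2 fold change of 0.99 ± 0.16 (SE), and with HMOX1 made the 2 higher members of 15 SPP1 macrophage genes, of which 3 were lower. Of 26 MAPK and EGFR feedback targets, 5 were higher, with DUSP5 at 1.78, DUSP1 at 0.66 and MYC at 0.54, and 5 were lower, with TGFA at -0.96. Of 24 cholesterol genes, 3 were higher and 0 lower, with MSMO1 at 1.53, INSIG1 at 1.20 and IDI1 at 0.91. The groups overlapped for IDI1. It lost its call in edgeR without labelled control replicate 3 or any labelled DCBLD2 replicate (adjusted p of 0.0519 to 0.153). MSMO1 and INSIG1 lost theirs without labelled DCBLD2 replicate 2 (0.0708 and 0.0811). Of 17 collagens and matrix genes, 5 were higher, with HSPG2 at 0.94, and 5 lower, with TNC at -2.12, COL6A1 at -1.10 and COL6A2 at -0.90. Of 14 epithelial genes, 0 were higher and 4 lower: MUC1 at -1.25, CLDN1 at -1.24, KRT18 at -0.56 and DSP at -0.54. Of 27 mesenchymal genes, 4 were higher, with ZEB1 at 1.04, and 6 lower, with MYL9 at -0.78 and MMP14 at -0.52.

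Among regulators of growth in H1299, 4 of 36 cell cycle genes were higher (TOP2A at 0.79) and 5 lower (GINS2 at -0.99, PCNA at -0.55, MCM3 at -0.53). Of 19 p53 targets, 1 was higher and 5 lower, with PLK2 at -1.09, TP53I3 at -0.79, AEN at -0.63 and GADD45A at -0.43. Of 21 YAP and TEAD targets, 3 were higher (CCN2 at 0.71) and 2 lower (NT5E at -0.68, AMOTL1 at -0.48). Of 32 hypoxia and glycolysis genes 4 were higher (KDM3A at 0.79, SLC2A3 at 0.67, ADM at 0.61) and 2 lower (PKM at -0.50). Of 16 lipid efflux genes, 1 was higher (FASN at 0.72) and 2 lower (PPARG at -1.01, CPT1A at -0.51). The groups overlapped for FASN, at an adjusted p of 0.0474 by edgeR. FASN lost its call in edgeR without labelled control replicate 3 or any labelled DCBLD2 replicate (adjusted p of 0.0592 to 0.161). Of 24 carcinoma-cell genes 4 were higher and 5 lower, DCBLD2 among them.

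Of 25 interferon response genes, 5 were higher (IFIT1 at 0.73) and 2 lower (IFI35 at -0.49, OAS3 at -0.43). Of 25 NF-kB targets, 1 was higher and 3 lower (IRF1 at -0.80, TRAF1 at -0.65, PLAU at -0.33). Of 13 checkpoint genes, 1 was higher (ARG2 at 1.24) and 3 lower (SIRPA at -2.36, NT5E at -0.68, CD276 at -0.50). Of 14 macrophage-acting factors 1 was higher (SPP1) and 1 lower (TGFB2 at -1.17). Of 6 chemokines 1 was higher (CXCL2). Of 7 M1-type genes, 1 was higher (IL12A at 1.48) and 3 lower (IRF5 at -1.32, CD40 at -1.10). Of 6 M2-type genes 3 were lower (TGM2 at -1.70, PPARG, IL4R at -0.65). Of 7 macrophage identity genes 2 were higher (ITGB2 at 2.54, CD68 at 0.50) and 1 lower (TYROBP at -1.92). None of 19 MHC class I genes was called, with B2M at -0.46 (adjusted p of 0.0663) and PSME1 at -0.42 (adjusted p of 0.0735) as values, and none of 32 ribosomal protein genes, with RPL4 at -0.24 and RPL7 at 0.24. Of 13 mitochondrially encoded genes 1 was lower (MT-CO3 at -0.36). MHC class II genes (2 of 4 higher, HLA-DMB at 1.96 and HLA-DMA at 1.34), myeloid genes (1 of 4 higher, 1 lower) and lymphocyte and endothelial genes (0 of 3 called, PECAM1 at -2.08, VWF at -2.03) had too few members for the list test. ITGB2, HLA-DMB and SIRPA were low, with no group mean above 1.19 TPM. ITGB2 went from 0.267 to 0.663 TPM, a smaller rise than in counts. With limma on log2(TPM + 1), an alternative chosen after seeing the data, 5 of the 96 genes lost their call: ITGB2 (adjusted p of 0.0773), SIRPA (0.0863, at -0.30), MMP2 (0.0786), DSP (0.108) and AMOTL1 (0.0505). SIRPA also lost it in edgeR without labelled DCBLD2 replicate 2 (adjusted p of 0.0782). HLA-DMB lost its call in edgeR without labelled control replicate 3 or labelled DCBLD2 replicate 1 or 2 (0.0676 to 0.115). HLA-DMA lost its call without labelled control replicate 3 or labelled DCBLD2 replicate 2 or 3 (0.0516 to 0.0880). IFIT1, and HMOX1 and PDIA6 given above, lost theirs without labelled control replicate 3 or any labelled DCBLD2 replicate (0.0505 to 0.111). Calls without such a mark can rest on single libraries too. PPARG and CD40 lay near the threshold, at adjusted p of 0.0491 and 0.0407, and lost their calls with DESeq2 (0.0521 and 0.0590), where IDI1 lost its call too (0.0822). PPARG lost it in edgeR without any 1 sample except labelled control replicate 1 (adjusted p of 0.0579 to 0.183), and CD40 without any except labelled DCBLD2 replicate 3 (0.0532 to 0.148).

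Adjusted over the list alone, the higher and lower counts in H1299 were 2 and 4 for SPP1 macrophage genes, 2 and 3 for M1-type, 0 and 4 for M2-type, 7 and 3 for interferon, 1 and 4 for checkpoint, 5 and 5 for cell cycle, 2 and 0 for cholesterol, 1 and 4 for lipid efflux and 2 and 4 for epithelial genes. They were 5 and 6 for mesenchymal genes, 6 and 5 for collagens and matrix, 7 and 5 for MAPK and EGFR feedback, 5 and 5 for carcinoma-cell genes and 0 and 0 for mitochondrially encoded genes, and the other lists kept their counts, apart from angiogenic factors and the stress response list given above. The median and the mean differed in sign in H1299 for SPP1 macrophage genes (0.05 and -0.05), angiogenic factors (0.14 and -0.07), macrophage identity (-0.07 and 0.15), macrophage-acting factors (-0.06 and 0.07), hypoxia and glycolysis (-0.04 and 0.05), mesenchymal genes (0.0016 and -0.04), collagens and matrix (0.02 and -0.12) and myeloid genes (-0.23 and 0.04). The test took the sign of the mean for macrophage identity, macrophage-acting factors, hypoxia and collagens, and that of the median for the other tested lists of these.

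In THP-1 cells, type I interferon response genes were higher in the labelled DCBLD2 group. Of 38 interferon genes, 36 were higher, 0 lower and 2 not called, with a median log2 fold change of 1.41 and an adjusted p of 1.61e-13 (camera), and the call held with an estimated correlation (adjusted p = 0.0433). IFI27, an interferon-inducible mitochondrial protein, rose from 48.5 TPM ± 1.51 to 456 TPM ± 7.59 (SD, n = 3), a log2 fold change of 3.27 ± 0.04 (SE). OAS3 (1.79), IFITM3 (1.57) and IFI6 (1.15) rose as well, and IFI44 (3.97), TRIM22 (3.16), IFITM1 (2.98) and MX1 (2.77) were among the 10 largest rises. Adjusted over the list alone the count was again 36. The shares of reads from mitochondrially encoded genes (3.48% to 3.51% in labelled control, 2.46% to 2.58% in labelled DCBLD2) and from the ribosomal protein list (2.07% to 2.08% against 2.85% to 2.97%) moved with the same groups, and so with every THP-1 gene group given here. The labels give no batch that crosses the groups.

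**Figure D2:**
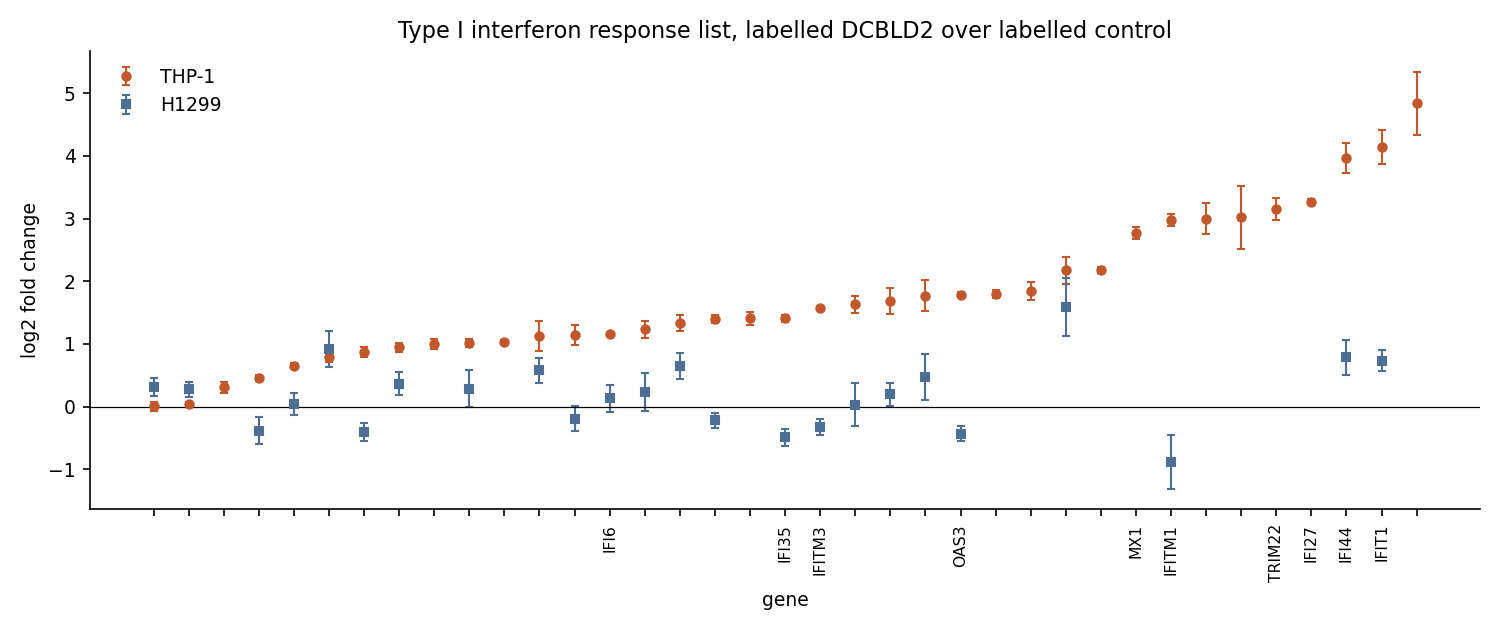
Log2 fold change (labelled DCBLD2 over labelled control) of each tested gene of the type I interferon response list, except 1 not reported here, in THP-1 (circles) and, where tested, H1299 (squares), with bars for the SE and labels on genes that the rule for named genes takes. In THP-1, 36 of the 38 tested genes were called higher, and in H1299 5 of 25, and the difference between the lines was not tested for the list.

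The other largest rises in THP-1 were SIGLEC1, the sialic-acid receptor CD169 of macrophages (log2 fold change 4.0 ± 0.18, SE), the proteoglycan VCAN (3.58), IGFBP5 (2.85), the lipid receptor TREM2 (2.78) and CYSLTR1 (2.74). TREM2 went from 18.4 TPM ± 1.14 to 124 TPM ± 5.13 (SD, n = 3). The largest falls were PTK7 (-3.19), EXOC3L2 (-3.13), the cytolytic protein PRF1 (-3.12), the chemokine CCL22 (-3.05), RGPD5 (-2.71), CAND2 (-2.60), CD300LB (-2.56), DUSP13 (-2.50), the secreted chaperone CLU (-2.48) and SPIB (-2.46). RGPD5 has near-identical copies, so its count is uncertain, and its call was lost with all 12 samples in one edgeR fit (adjusted p of 0.128). In TPM the changes of TRIM22 (1.21 to 5.30), SPIB (5.26 to 1.53) and RGPD5 (4.39 to 2.03) were smaller than in counts.

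SPP1 was at 2381 TPM ± 31.2 (SD, n = 3) in THP-1 labelled DCBLD2 and 2216 TPM ± 12.4 (SD, n = 3) in labelled control, a log2 fold change of 0.15 ± 0.01 (SE) or 1.11-fold, with an adjusted p of 2.08e-10 by edgeR. Its call was lost in a setting chosen after seeing the data, with an adjusted p of 0.490 by edgeR's likelihood ratio test. That setting put the larger common spread of the H1299 libraries in place of the gene's own. In the other alternatives the adjusted p of SPP1 lay between 4.06e-25 and 0.0341. The gene (ENSG00000118785) lies on chromosome 4, 87975650 to 87983426, on the plus strand. Of 24 SPP1 macrophage genes, 12 were higher, with TREM2 and FABP4 (1.25), and 12 lower, with the chitinase-like protein CHI3L1 (-0.95) and the protease CTSB (-0.75). The list was not called (adjusted p = 0.636). Of 34 angiogenic factors, 14 were higher and 15 lower (adjusted over the list alone 14 and 16), with TYMP at 1.23, THBD at -0.67 and PLAUR at -0.52, and that list was not called either (adjusted p = 0.703).

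In all, 4528 genes were higher and 4413 lower of 13120 tested in THP-1, which is 68.1% of genes, and 516 and 493 changed at least 2-fold. The groups did not overlap for 71.0% of genes, where chance gives 10%. Replicates lay close to sampling noise here. The coefficient of variation beyond counting noise, common to all genes (square root of edgeR's common dispersion), was 1.96% against 13.3% in H1299. With the common spread of H1299 for every gene and a likelihood ratio test the count was 4531. That setting was chosen after seeing the data and changes the test as well as the spread.

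Of 28 lists tested in THP-1, 5 were higher and 3 lower, against 3 to 5 lists in the 9 other splits of the 6 libraries, and the interferon list alone kept its call with an estimated correlation. Of 36 cell cycle genes, 33 were higher and 2 lower, with a median of 0.71 and an adjusted p of 4.94e-06 (adjusted p = 0.0630 with an estimated correlation). TYMS (1.18), E2F1 (1.14) and MCM7 (0.55) rose, and the mitotic kinase AURKA fell by 0.81 on the log2 scale. Of 22 collagen and matrix genes, 2 were higher and 15 lower, with a median of -0.69 and an adjusted p of 2.92e-05 (adjusted p = 0.0693 with an estimated correlation): COL4A2 (-1.52), COL6A3 (-1.43), HSPG2 (-1.05) and COL6A1 (-0.71). Of 18 MHC class I genes, 13 were higher and 3 lower (median 0.30, adjusted p = 0.00590, and adjusted p = 0.176 with an estimated correlation), with HLA-B and HLA-E at 0.49, and the chaperone CALR at -0.52. Of 26 MAPK and EGFR feedback targets, 6 were higher and 16 lower (median -0.22, adjusted p = 0.0142, and adjusted p = 0.196 with an estimated correlation), with DUSP5 at -0.67, DUSP1 at -0.54, DUSP6 at -0.45 and IER3 at -0.44.

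Ribosomal and mitochondrial transcripts moved with the THP-1 groups. Of 32 ribosomal protein genes, 27 were higher and 4 lower (median 0.53, adjusted p = 1.57e-12, and adjusted p = 0.308 with an estimated correlation), with RPS14 and RPL35 at 1.05 and RPS2 at 0.66. Of 13 mitochondrially encoded genes, 1 was higher and 12 lower (median -0.53, adjusted p = 1.26e-08, and adjusted p = 0.220 with an estimated correlation), with MT-ND2 at -0.92, MT-ND4 at -0.66, MT-ND5 at -0.63 and MT-CO1 at -0.59. Without both classes in the fit, 8916 genes were called, an alternative chosen after seeing the data.

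Of 24 myeloid genes, 15 were higher and 6 lower in THP-1 (median 0.44, adjusted p = 0.0275, and adjusted p = 0.196 with an estimated correlation): CD14 rose by 1.49, CORO1A by 1.43, TYROBP by 1.03 and FCER1G by 0.83 on the log2 scale. Of 27 macrophage identity genes, 14 were higher and 8 lower, the integrins ITGAM (-0.87) and ITGAX (-0.80) among the latter, and the list was not called. Neither M1-type genes (10 higher, 5 lower of 18, TNF at 0.86, IL1B at -0.22, CCL20 at -0.31, CCR7 at -2.10) nor M2-type genes (7 higher, 6 lower of 16, CCL22, IL1RN at -0.93, MERTK at -0.90, TGM2 at -0.47) were called as lists. IL1B held the largest share of estimated reads in every THP-1 library (1.91% to 2.16%).

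The remaining THP-1 lists were not called. Chemokines (8 higher, 9 lower of 19) included CXCL1 at 0.51 and CXCL8 at -0.24. Macrophage-acting factors (11 higher, 11 lower of 23) included MIF at 0.94, GDF15 at -1.04, CSF1 at -0.78 and LIF at -0.63. Checkpoint genes (8 higher, 8 lower of 19) included LGALS1 at 1.65, LGALS9 at 0.84, LILRB1 at -0.98 and TGFB1 at -0.25. NF-kB targets (18 higher, 9 lower of 30) included PLAU at 0.67 and CD83 at -0.69. MHC class II genes (4 higher, 3 lower of 9) included HLA-DRB1 at 1.24, HLA-DRB5 at 1.05, CTSS at 0.49 and CD74 at 0.20. Stress response genes (9 higher, 15 lower of 27) included PHGDH at 1.90 and ATF4 at 0.81 but HSPA5 at -0.87 and ATF3 at -0.84. Hypoxia and glycolysis genes (12 higher, 15 lower of 34) included DDIT4 at 1.07, TPI1 at 0.57, GAPDH at 0.49 and ALDOA at 0.47. Cholesterol genes (9 higher, 5 lower of 24) included HMGCS1 at 0.57, STARD4 at 0.44, FDPS at 0.33 and SQLE at -0.62. Lipid efflux genes (8 higher, 8 lower of 19) included APOC2 at 1.08, NR1H3 at -1.18 and PLIN2 at -1.01. P53 targets (6 higher, 7 lower of 19) included CDKN1A at 0.18, TNFRSF10B at -0.52 and PLK3 at -0.33. YAP and TEAD targets (8 higher, 9 lower of 20) included IGFBP3 at 0.61, MYOF at 0.58, AXL at -1.52 and ASAP1 at -0.30. Mesenchymal genes (10 higher, 8 lower of 26) included S100A4 at 1.04 and ITGA5 at -0.54. Epithelial genes (3 higher, 2 lower of 9) included CLDN1 at 1.19, CLDN7 at 0.49, LAMB3 at -0.73 and OCLN at -0.66. Lymphocyte and endothelial genes (0 higher, 5 lower of 6) included VWF at -1.80, CD79A at -1.40, NKG7 at -0.41 and PECAM1 at -0.16. With all 12 samples in one edgeR fit, 7 of 117 THP-1 genes chosen by the rule for naming lost their call, RGPD5 and 6 of these lists: HMGCS1 (adjusted p of 0.189), STARD4 (0.111), FDPS (0.273), CDKN1A (0.338), NKG7 (0.114) and PECAM1 (0.614). NKG7 lost it without labelled control replicate 1 or 3 or labelled DCBLD2 replicate 2 (0.0524 to 0.0892) and with DESeq2 (0.0837). OCLN lost it without labelled control replicate 3 or labelled DCBLD2 replicate 1 or 2 (0.0778 to 0.0817), with DESeq2 (0.0569) and with limma on log2(TPM + 1) (0.0527).

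Adjusted over the list alone, the higher and lower counts in THP-1 were 8 and 10 for chemokines, 8 and 9 for checkpoint genes, 10 and 15 for stress response genes and 14 and 16 for angiogenic factors, and the other lists kept their counts. The median and the mean differed in sign for M2-type genes (0.07 and -0.16), stress response genes (-0.14 and 0.05), p53 targets (0.05 and -0.11), epithelial genes (-0.05 and 0.09) and mesenchymal genes (0.05 and -0.08). The test took the sign of the mean for M2-type genes and p53 targets and that of the median for the others of these. For macrophage-acting factors (median 0.15, mean 0.03, test lower), checkpoint genes (-0.08, -0.02, test higher) and lipid efflux genes (-0.00066, -0.03, test higher) the test took the opposite sign to both.

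**Figure D3:**
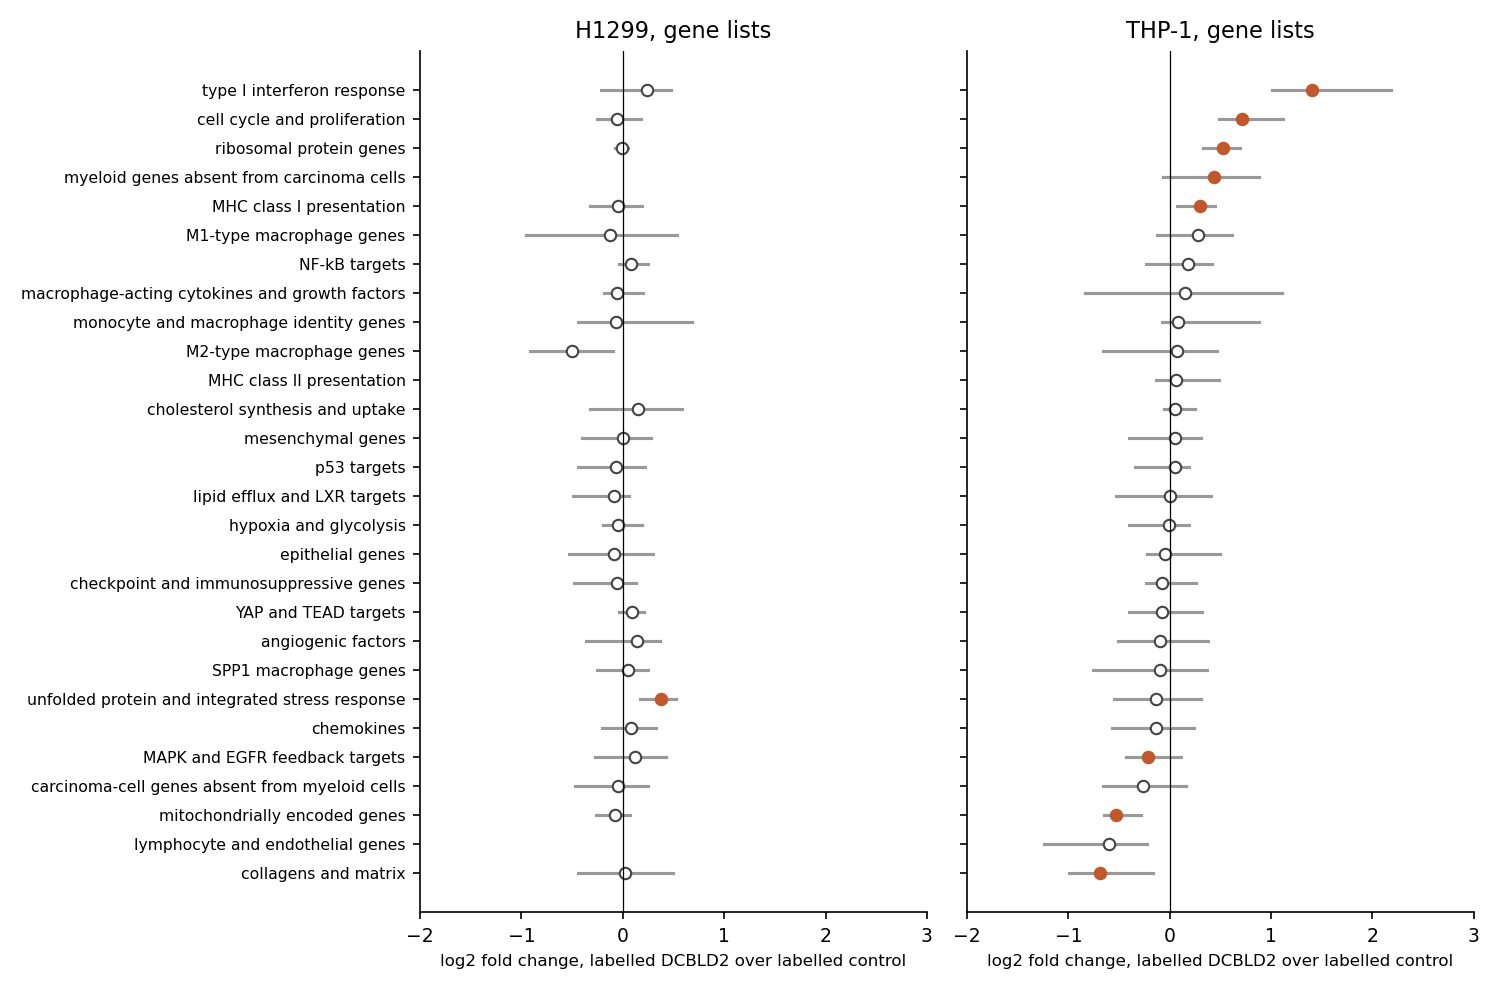
Median log2 fold change (labelled DCBLD2 over labelled control) of each gene list with at least 5 tested members in H1299 and THP-1, with grey bars from the lower to the upper quartile of its genes. Filled circles mark lists called by camera with the preset correlation, 1 of 25 in H1299 and 8 of 28 in THP-1, and in THP-1 the interferon list lies farthest from 0, at 1.41.

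The genes called in H1299 were compared with those called in THP-1 over 11631 genes tested in both. No pair of directions was enriched: 446 genes were higher in both where 425 were expected by chance, 389 were lower in both where 407 were expected, and the odds ratios of the 4 pairs lay between 0.93 and 1.11 (Fisher's exact test, two-sided, adjusted p of 0.248 for each). With direction ignored, a test chosen after seeing the data, 1714 genes were called in both where 1665 were expected, an odds ratio of 1.13 with a p of 0.0162. Among genes changed at least 2-fold, 2 of the 4 pairs were above chance, with 12 genes higher in both (4.61 expected, adjusted p of 0.00455) and 20 genes higher in H1299 and lower in THP-1 (3.66 expected, adjusted p of 2.45e-09). The pairs that did not pass held 9 genes lower in H1299 and higher in THP-1 (5.66 expected, adjusted p of 0.189) and 9 lower in both (4.50 expected, adjusted p of 0.0628). Across genes, which are not independent replicates, the fold changes of the cell lines had a Pearson r of 0.0167 and a Spearman rho of -0.0173.

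Carcinoma-cell RNA was looked for in the THP-1 libraries. The carcinoma list averaged 1.79 ± 0.10 in labelled DCBLD2 and 1.88 ± 0.0472 in labelled control (SD, n = 3, log2 CPM), a difference of -0.09 (exact permutation test, two-sided, p of 0.3, where 0.1 is the smallest possible), and 10 of its 18 tested genes were lower and 4 higher, TPM2 at -0.62 among them. The keratins KRT18 and KRT8 were seen in THP-1 labelled DCBLD2 at 0.107% and 0.114% of their H1299 level. In TPM, KRT18 was at 1.01 ± 0.561 (SD, n = 3) there and 0.204 ± 0.0433 (SD, n = 3) in labelled control, and KRT8 at 0.524 ± 0.12 and 0.283 ± 0.193, against the direction of the list mean. Over 51 genes abundant in H1299 and nearly silent in THP-1 labelled control, the median share was 0.104% and the highest 0.337%, and the median share in labelled control was 0.0637%. The genes were chosen for lying under 0.3 CPM in labelled control, which holds down the share of that group alone. The shares of the groups therefore cannot be compared. The medians of the carcinoma list differed by 0.0064 in the opposite direction to the means (exact permutation p of 1). The list holds genes that THP-1 cells themselves expressed, DCBLD2 and AXL among them. Its mean and median therefore cannot detect carry-over at shares this small.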

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

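The tests of DCBLD2 and of KRTAP4-7, and that of a coinciding batch, were chosen after the results were seen, and those of GC content, of carried-over RNA in the interferon list and of other splits were written before. Of the 15 genes named in both cell lines, 9 were called in opposite directions, and the difference between the contrasts passed the threshold in one edgeR fit of all 12 libraries. For the 8 reported here, the difference, THP-1 minus H1299 in log2 fold change, was 2.94 for TYROBP, -2.46 for DUSP5, 2.41 for CLDN1, 2.21 for OAS3, -2.01 for HSPG2, -1.99 for HSPA5, -1.21 for DUSP1 and 0.98 for PLAU. HSPA5 rose by 1.11 in H1299 and fell by 0.87 in THP-1. Of 14244 genes tested for such a difference, 5518 passed. Opposite calls were also common over all 11631 genes tested in both lines. There, 423 genes were higher in H1299 and lower in THP-1, and 456 were lower in H1299 and higher in THP-1. Calls in the same direction were 446 higher in both and 389 lower in both. PECAM1 and VWF, among the 15, were not called in H1299. The contrasts differ in kind, a genotype label in H1299 and an exposure in THP-1, so opposite directions do not conflict. The fit of all 12 libraries shares each gene's spread between cell lines. The common coefficient of variation beyond counting noise was 1.96% in THP-1 and 13.3% in H1299. In that fit the H1299 calls rose from 2669 to 5056, so it may understate the H1299 spread and pass too many genes. TYROBP had a low level in H1299, at 2.56 TPM in labelled control. Some of the H1299 calls rest on single libraries. TYROBP (adjusted p of 0.0641 to 0.137) and PLAU (0.0562 to 0.147) lost theirs in edgeR without labelled control replicate 2 or 3 or labelled DCBLD2 replicate 1 or 2. OAS3 lost its call without any of these or labelled DCBLD2 replicate 3 (0.0570 to 0.115), and DUSP1 without labelled DCBLD2 replicate 2 (0.0506).

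DCBLD2 was lower in the H1299 libraries labelled for its overexpression. Scaling is argued against, since the log2 fold change closest to 0 over all settings tried was -0.96. An added copy whose reads were not counted cannot be tested, because gene totals hold no such reads. For an exchange of the H1299 labels, the DCBLD2 length was estimated from the ratio of reads to TPM. On the log2 scale, relative to the median gene, it was 0.73 ± 0.0893 in labelled DCBLD2 and 0.99 ± 0.0498 in labelled control (SD, n = 3). A shift as large as this -0.26 was reached by 2.22% of genes. Exchanged labels would shorten the length in labelled control if the introduced copy lacks untranslated regions, which is not known. The shift goes the other way, against an exchange on that condition only, and another choice of transcripts could shift the length too. An exchange and an uncounted copy therefore cannot be told apart. A real fall of the endogenous gene stays open too, and no test here speaks to it.

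The interferon list rose in THP-1 labelled DCBLD2. A bias of GC content or length is argued against, because the median of the list was 1.41 before and 1.20 after the trend with GC content, transcript length and level over 13041 genes was removed. RNA carried over from H1299 is argued against as the source of these reads. At the highest share seen it accounts for a median of 0.152% of the rise of the 36 genes, and for at most 7.88%. Whether carried-over RNA acted on the THP-1 cells was not tested. A culture or library batch that coincides with the group cannot be told apart from the exposure, since the labels give no batch that crosses the groups and the 68.1% of genes that changed does not decide it. An effect of the exposure named by the design stays open as a hypothesis.

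KRTAP4-7 was near 0 in labelled control libraries and present in labelled DCBLD2 libraries of both cell lines, with 188 to 360 reads per H1299 library and 11 to 16 per THP-1 library. It was the 1 gene with this pattern in both lines. Carry-over into THP-1 at the share of other genes is argued against, because their highest share would give 3.43 reads where 40 were counted (Poisson p of 1.11e-28, counting error only). Those genes had to lie under 0.3 CPM in THP-1 labelled control, which limits the share they can show. A larger share for this transcript alone is not excluded. Reads split with the other annotated KRTAP4 genes are argued against, because none of these had more than 1 read over the 12 libraries, and of 94 KRTAP genes 2 had more than 10 reads, KRTAP4-7 and KRTAP2-3, of which KRTAP2-3 had 0 in THP-1. Sequence of an introduced construct may be a source, and it cannot be told apart from expression of the gene without read positions.

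Other splits of the 6 libraries of a cell line were counted, and with 10 splits no share under 0.05 is possible. Each other split puts libraries of both groups on each side, so a group difference from any source adds to its spread. Low counts of genes in those splits therefore do not measure a chance level. In H1299 the labels gave 2669 genes and the highest other split 0 (edgeR; at an unadjusted p under 0.05, 4759 against 39 to 811), and 1 of the 10 splits, the real one, gave as many. In THP-1 the labels gave 8941 genes and the highest other split 0 (unadjusted 9267 against 42 to 78), again 1 of 10. For lists, all 10 splits gave at least the 1 list of the labels in H1299, with up to 7 in another split, and in THP-1 the labels gave 8 and the highest other split 5.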

How the results depend on the processing

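Settings named as added were chosen after seeing the data: the spread of the other cell line, the fit without ribosomal protein and mitochondrially encoded genes, limma on log2(TPM + 1), and the overlap with direction ignored. The first of these used the common spread of the other line for every gene with a likelihood ratio test. It thus changed the test as well as the spread. The cause was not tested for any shift below unless stated.

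In H1299 the 2669 calls became 5056 with all 12 samples in one fit, 447 with the 2-fold threshold and 9051 with the THP-1 spread (added), and lay between 514 and 3158 without 1 sample. In THP-1 the 8941 calls became 1009 with the 2-fold threshold and 4531 with the H1299 spread (added), and lay between 8467 and 8719 without 1 sample. Of the main calls, 505 remained in H1299 without labelled DCBLD2 replicate 2, and 4499 in THP-1 with the H1299 spread. DCBLD2 in H1299 kept its direction and call in every setting, between -1.45 and -0.96. SPP1 in THP-1 kept its direction, and lost its call at 0.15 with the H1299 spread. With that setting 11 of 117 other named THP-1 genes lost their call too (adjusted p of 0.0917 to 0.442, likelihood ratio test). These were IL1B, CXCL8, TGFB1, CCL20, CD74, PLK3, FDPS, CDKN1A, PECAM1, ASAP1 and NKG7. In H1299 the replicate numbers did not pair the samples. Same-numbered samples correlated at -0.134, -0.340 and -0.333, so the block there joined samples with negative correlations, and no sample correlated best with its own number. In THP-1 same-numbered samples correlated at 0.0873, 0.111 and 0.0425. There every sample correlated best with its own number, a hint of pairing from the data only. With the replicate block 1797 and 8990 genes were called. Under it 13 of 96 named H1299 genes were not called (adjusted p of 0.0536 to 0.121), among them OAS3, PLAU, PDIA6, HMOX1, MT-CO3, GADD45A, IFI35, CD276, PPARG and CD40, and 0 of 117 in THP-1.

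Of 25 lists in H1299, 1 was called, 0 with an estimated correlation, 2 with the replicate block, 0 with the block and fry, and 1 to 3 without 1 sample; fry called 1 list, M2-type genes. Of 28 lists in THP-1, 8 were called, 1 with an estimated correlation, 27 with fry, 25 with the block and fry, and 8 without any 1 sample. Fry tests no list against other genes, and with it 4 THP-1 lists passed its threshold in the opposite direction to camera, at medians of -0.0088 for hypoxia and glycolysis (-0.0086 with the block), 0.056 for cholesterol genes, -0.00066 for lipid efflux and -0.081 for YAP and TEAD targets (-0.073 with the block).

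No pair of directions of the overlap was called (0 of 4), but 2 were with the 2-fold threshold, at odds ratios of 2.80 (higher in both) and 6.53 (higher in H1299, lower in THP-1), and 2 without a filter, at 1.44 (higher in both) and 1.36 (lower in H1299, higher in THP-1). With direction ignored (added) the odds ratios were 1.13, 3.18 with the 2-fold threshold, 1.53 without a filter and 1.12 with a mean of 10 counts. The carried-over carcinoma list differed by -0.09 as a mean and 0.0064 as a median. Of single named genes, 0 reversed: over 96 in H1299, 132 gene and setting pairs lost a call, 45 of them without labelled DCBLD2 replicate 2, and 26 gained one, and over 117 in THP-1, 27 lost one. In H1299, 50% of simulated 1.5-fold changes were recovered, and no test of depth was run.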

Other observations

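Of the 4 gene groups described here, all were drawn up after the data had been seen, around members such as HSPA5 and PHGDH. Camera was run on them in both cell lines (8 tests), and its p-values are not used, because genes already seen to change were kept in. The counts and values below describe single genes and carry no test of a group.

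Among serine and one-carbon enzymes, 7 of 8 were higher and 1 lower in THP-1 labelled DCBLD2, with a median log2 fold change of 0.75. PHGDH, PSAT1 and PSPH, the enzymes of serine synthesis, rose by 1.90, 1.29 and 0.88, ALDH1L2 by 1.41, and the cytosolic SHMT1 fell by 1.16. In H1299, 1 of the 8 was higher, MTHFD2 at 0.60, and 1 lower, SHMT1 at -0.46, and 6 were not called.

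Among endoplasmic reticulum chaperones and folding enzymes, 4 of 14 were higher, 0 lower and 10 not called in H1299, and 0 were higher, 11 lower and 3 not called in THP-1. PDIA4 was at 0.44 in H1299 and -0.88 in THP-1, and HYOU1 at -0.73 in THP-1. Among heat-shock genes, mitochondrial chaperonins included, 6 of 12 were higher and 0 lower in H1299, with HSP90AA1 at 1.34, HSPH1 at 0.82 and the chaperonin HSPD1 at 0.62, and 5 were higher and 5 lower in THP-1. Among genes of lysosomal enzymes, membrane and transport proteins, 4 of 19 were higher and 13 lower in THP-1, with the cholesterol transporter NPC1 at -1.09 and the lipase LIPA at -0.79, and 2 of 18 were higher and 2 lower in H1299.

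Several genes were near 0 in every library of one group and counted in every library of the other, and were chosen after their values were seen. In H1299, RPS6KA2 had 31 to 40 reads per library in labelled control and 0 in labelled DCBLD2, IHO1 had 75 to 106 against 0 to 1, AFAP1L2 11 to 24 against 0 to 1, and CAMK1 11 to 14 against 0 to 1. In THP-1, ANK3 had 0 to 1 reads in labelled control and 17 to 23 in labelled DCBLD2, FAM111B 0 to 1 against 13 to 24, MCF2L 0 to 1 against 12 to 22, RBM20 0 to 1 against 13 to 22, and ETV7 0 to 2 against 13 to 19.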
